A study of Homo sapiens with 12 samples.

How the data were processed

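RNA abundance was measured by sequencing in 12 libraries from HEK293T cells, a human embryonic kidney line that expresses the SV40 large T antigen. Cells had been transfected for 24 hours with an empty vector, with wildtype ANT1, or with ANT1 carrying 3 substitutions (A90D, L98P and A114P, the triple mutant) or 4 (these and A123D, the quadruple mutant). ANT1 is the adenine nucleotide translocator of the inner mitochondrial membrane encoded by SLC25A4. Per the labels, each of the 4 groups held 3 wells plated in triplicate from 1 line, so the p-values measure only the spread between wells, part of which may be technical. RNA was extracted from whole cells and made into stranded libraries of polyadenylated RNA, per the labels' protocols.

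The deposited values are RPKM (reads scaled by gene length and by library depth), made by the authors, and each library came with 1 value for each of 27103 gene names. The submitters' processing notes name TopHat 1.1.0, Partek and the build hg19. The role of each tool, the gene annotation, the counting mode and the use of strand are not given in the sources used here. Low RPKM values moved in steps. With the span of each gene from start to end, introns included, taken from an annotation of GRCh38.p14 that covered 94.5% of names, 80.3 to 81.5% of low values per library lay within 0.1 of a whole read, against 17.5 to 20.5% when spans were shuffled between genes. The values therefore divide reads by the whole gene span, so RPKM of genes with long introns are small and levels of different genes are not comparable. The steps gave a depth of 17350000 to 24330000 reads per library. The RPKM summed to 73361.2 to 78474 per library, and 20586 names had a value above 0 in at least 1 library. Names in 28 cases had been turned into dates by a spreadsheet, and 4 of these were ambiguous, so none of them was named. Genes encoded by mitochondrial DNA were not analysed here. Genes with near-identical copies are called uncertain, as are antisense genes, because the counting rule for shared reads and strand is unknown.

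The tests, the groups, the gene lists, the naming rule and most alternatives were fixed before the data were examined. That plan allowed for raw counts or for normalised values, and the RPKM unit led to the second. Differences were tested with limma 3.58.1 in R 4.3.3 (linear models with moderated variances and a mean-variance trend) on log2(RPKM + 1), so a fold change is on the log2(RPKM + 1) scale and understates the change of low genes. All 12 libraries entered 1 fit. Genes with at least 1 RPKM in at least 3 libraries were tested, which left 6645, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Groups that did not overlap were found for 13.6 to 24.7% of tested genes, depending on the comparison, against the 10% that chance gives for 3 against 3. Of 23 gene lists, 21 had at least 5 tested members and were tested against all other genes with limma's camera, with a preset inter-gene correlation of 0.01 and adjustment over the lists. Camera with an estimated correlation and fry, which asks whether a list moves one way without comparing it with other genes, were run as alternatives. The genes named are SLC25A4, SLC25A5, SLC25A6 and SLC25A31. To these were added the 10 largest called changes in each direction against vector, or 5 between constructs, that had at least 1 RPKM in the higher group and groups that did not overlap. Up to 4 members of each list with the lowest adjusted p completed the rule.

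The same replicate number did not mark a shared origin in the labels. Deviations of same-numbered libraries from their group means correlated in each pair only between quadruple and triple mutant (0.138, 0.201 and 0.115), and that comparison was also fitted with the number as a block. The block gave each number an effect shared by all 12 libraries, so it did not model a pairing of the mutant libraries alone. Alternatives were median centring of each library, no variance trend, no filter, a minimum of 5 RPKM, pseudocounts of 0.1 and 5, a fit of only the 2 groups compared, the replicate block, leaving SLC25A4 out of the totals, an absolute log2 fold change of at least 1, and leaving out each of the 12 libraries. After the data had been seen, 3 kinds were added. The first was voom, limma's test for counts, on reads estimated from RPKM, span and depth (at least 10 in at least 3 libraries). The others removed from each library a lowess trend (span 0.3) of its deviations with transcript GC content or with transcript length, known for 98.2% of tested genes. In data simulated for quadruple mutant against vector, the limma test called 88% of 50 genes changed 1.25-fold and 6% of 50 genes changed 1.1-fold. It called 4 of 6274 unchanged genes there, and 0 of 6504 genes in a simulated comparison of wildtype with vector without changes. Every simulated gene had the same spread beyond counting noise (dispersion 0.0013), with noise independent between genes and no GC trend. These rates therefore need not hold for the real libraries. Tables were handled in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.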

Results

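Transcript levels were compared between HEK293T cells carrying an empty vector, wildtype ANT1, a triple mutant of ANT1 (A90D, L98P and A114P) and a quadruple mutant that adds A123D, 24 hours after transfection, with 3 libraries per group. The series concerns stress from unimported mitochondrial proteins, and the comparisons ask what the cells transcribe when ANT1 is made in excess and when it also carries these substitutions. Depth was 17350000 to 24330000 reads per library, as estimated from the RPKM steps. Errors of levels are SD with n = 3, those of log2 fold changes are standard errors, and each adjusted p comes from limma. The first principal component, with 31.9% of the variance, held the 3 vector libraries at 4.55 to 7.45 and the other libraries between -4.02 and 0.481. Wildtype replicate 3 stood apart on the second (-6.04), and its deviations fell by 0.07 log2 units per 10% of transcript GC content, against slopes of -0.0274 to 0.0366 in the other 11 libraries.

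SLC25A4, the transfected gene, rose in every construct group. Its level was 5.46 ± 0.373 RPKM with vector, 416.1 ± 51.6 with wildtype ANT1, 792.4 ± 49.4 with the triple mutant and 1030 ± 58.6 with the quadruple mutant (SD, n = 3 each). The log2 fold changes against vector were 6.01, 6.94 and 7.32 (standard error 0.0807; adjusted p = 3e-14, 4.86e-15 and 2.49e-15). The mutants also exceeded the wildtype construct, by 0.93 for the triple (adjusted p = 0.000291) and 1.31 for the quadruple mutant (adjusted p = 5.11e-06). Quadruple over triple mutant was 0.38 (adjusted p = 0.0576), which was not called, although the test blocked on replicate number called it (adjusted p = 0.0244), as did the test without wildtype replicate 1 (adjusted p = 0.0485) or replicate 3 (adjusted p = 0.0047). Over 24 alternatives its adjusted p ran from 0.0047 to 0.314. The amount of construct mRNA thus differed in both comparisons of a mutant with the wildtype. Of the other ADP/ATP carriers, SLC25A5 was called in none of the 6 comparisons (log2 fold change 0.01 for quadruple mutant against vector, adjusted p = 0.937). SLC25A6 went from 72.4 ± 2.26 RPKM with vector to 83.3 ± 1.36 with the quadruple mutant, a rise of 0.20 (adjusted p = 0.0384), and was 0.29 above the wildtype construct (adjusted p = 0.0122). SLC25A31, the testis form, did not reach the minimum level for testing.

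**Figure D1:**
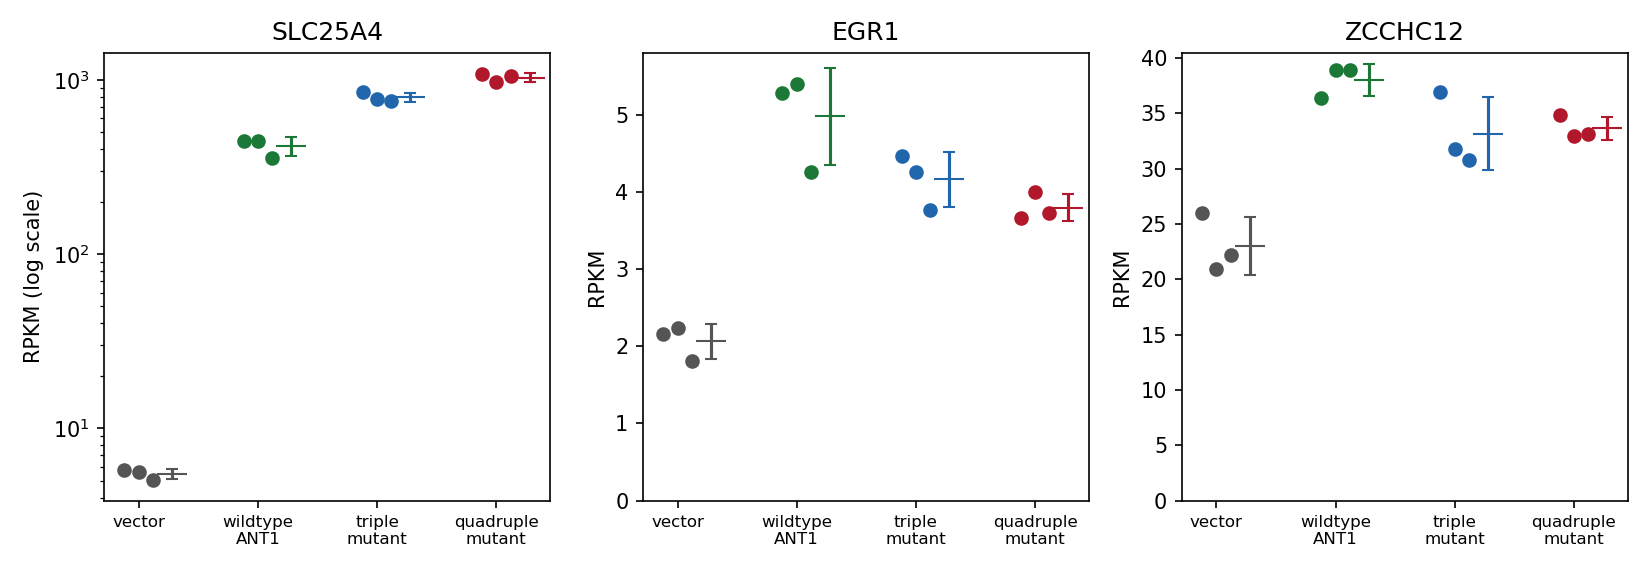
RPKM of SLC25A4 (log axis), EGR1 and ZCCHC12 in each library of the 4 groups, with points for the 3 libraries and, beside them, the group mean with SD. SLC25A4 rose from 5.46 with vector to 416.1, 792.4 and 1030 with the constructs, and the construct libraries of EGR1 and ZCCHC12 all lie above the vector libraries.

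Wildtype ANT1 against vector asks what an excess of the normal carrier does. EGR1, an immediate-early transcription factor, rose 2.41-fold, from 2.07 ± 0.226 to 4.98 ± 0.631 RPKM (log2 fold change 0.96 ± 0.0765, adjusted p = 5.48e-05). ZCCHC12, a zinc finger coactivator, rose 1.65-fold, from 23.0 ± 2.64 to 38.0 ± 1.46 RPKM (0.70, adjusted p = 0.00115). Among the largest decreases were MIR210HG, host transcript of the hypoxia-induced miR-210 (-0.70, adjusted p = 0.0302), DDIT4, a stress-induced inhibitor of mTORC1 (-0.59, adjusted p = 0.0342), and HILPDA, a lipid droplet protein induced by hypoxia (-0.43, adjusted p = 0.0342). In all 50 genes were called of 6645, 27 higher and 23 lower. Apart from SLC25A4 the median size of these changes was 0.264 log2 units, and no other called gene reached 1 on the log2(RPKM + 1) scale. Higher were also MIR503HG (0.49), the imprinted gene PHLDA2 (0.34), the receptor GPR50 (0.33), LOC90784 (0.30), GEMIN6 of the SMN complex (0.28), the paraspeckle protein SFPQ (0.28, adjusted p = 0.00321), the dolichol kinase DOLK (0.27) and cyclin D1, CCND1 (0.20). Lower were also CITED4 (-0.38), the linker histones HIST1H1C (-0.38) and H1F0 (-0.29), the transcription factors BHLHE40 (-0.36) and ATF3 (-0.32, adjusted p = 0.00217), NRN1 (-0.35) and the chemokine receptor CXCR4 (-0.30).

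The glycolysis and hypoxia list was called lower in wildtype ANT1 cells. Of 20 tested members 3 were called lower, the glycolytic enzymes GAPDH (-0.26, adjusted p = 0.0241), HK2 (-0.27, adjusted p = 0.0241) and ENO2 (-0.29, adjusted p = 0.0273), and 17 were not called. ALDOA was at -0.26 (adjusted p = 0.0594). Adjusted over the list alone, 14 members were lower and 0 higher, and the median was -0.156. Camera gave adjusted p = 7.09e-14 with the preset correlation and adjusted p = 0.276 with an estimated correlation. Cholesterol synthesis genes had a median of -0.069 over 23 members with none called or past the list-alone test, as in SCD (-0.12, adjusted p = 0.122). Camera called that list lower (adjusted p = 0.00222, but adjusted p = 0.0961 with an estimated correlation). Fry called both lists (adjusted p = 0.0305 for glycolysis and 0.00569 for cholesterol synthesis). Histone genes were called lower as a list (adjusted p = 0.00637, but adjusted p = 0.801 with an estimated correlation), with 2 of 11 members called and 3 adjusted over the list alone. Cytosolic heat shock genes rose as a list, with 21 of 28 members positive and a median of 0.055 (adjusted p = 0.00135, but adjusted p = 0.911 with an estimated correlation). The constitutive chaperone HSPA8 was the 1 member called (0.19, adjusted p = 0.0382), 4 passed when adjusted over the list alone, and DNAJA1 was at 0.18 (adjusted p = 0.0615). Mitochondrial protein import genes (median 0.052, adjusted p = 0.00637) and mitochondrial ribosome genes (median 0.039, adjusted p = 0.00135) were called higher with 0 members called of 27 and 73. The estimated correlation gave adjusted p = 0.911 and 0.925, and adjusted over the list alone 5 and 0 members were higher. In the heat shock, import and mitochondrial ribosome lists the median deviation of wildtype replicate 1 (-0.0372, -0.0421 and -0.0415) lay below that of vector replicate 1 (0.007, 0.00699 and 0.015), while vector replicates 2 and 3 lay lower still, at -0.0984 to -0.0441. The autophagy and aggrephagy list was not called (adjusted p = 0.103), with 0 of 23 members called, and the mitophagy receptor BNIP3 was at -0.31 (adjusted p = 0.0814). The integrated stress response list was not called either (adjusted p = 0.636), although ATF3 and DDIT4 belong to it. Markers of other cell types had 2 tested members, CD68 and COL1A1, and neither was called in any of the 6 comparisons.

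With single libraries left out, which also weakens the test, the number of genes called for wildtype ANT1 changed widely. It was 74 without wildtype replicate 3, 7 without wildtype replicate 2, 8 without vector replicate 2, 20 without vector replicate 1 and 25 without vector replicate 3 or quadruple replicate 1, and 6 genes, among them ATF3, EGR1, SFPQ, SLC25A4 and ZCCHC12, were called whichever library was left out. A fit of the 2 groups alone called 7 genes, and removing the GC trend of each library gave 108, with 42 of the 50 still called but not CITED4 (-0.38, adjusted p = 0.0549). The import list was lost without wildtype replicate 2 (adjusted p = 0.0888) or 3 (adjusted p = 0.0751), and the mitochondrial ribosome list without wildtype replicate 2 (adjusted p = 0.107).

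**Figure D2:**
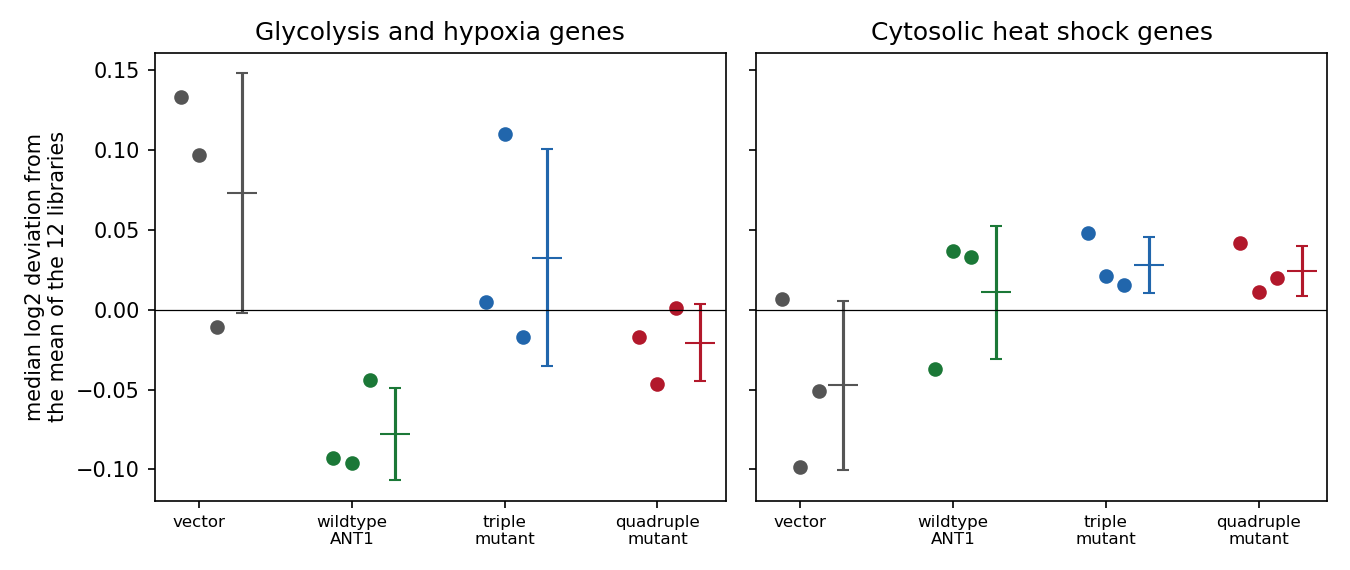
Median over the genes of a list of the log2 deviation from the mean of the 12 libraries, for glycolysis and hypoxia genes and for cytosolic heat shock genes, with points for the 3 libraries of each group and the group mean with SD beside them. The glycolysis and hypoxia list was lowest on average in wildtype ANT1 libraries, where its median fold change against vector was -0.156.

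The triple mutant against vector showed fewer called genes. EGR1 rose 2.02-fold to 4.17 ± 0.356 RPKM (log2 fold change 0.75, adjusted p = 0.00092), ZCCHC12 rose 1.44-fold to 33.2 ± 3.28 RPKM (0.51, adjusted p = 0.0343), and RBM12 rose by 0.23 (adjusted p = 0.0465). In all 15 genes were called, 4 higher and 11 lower, where centring each library on its median gave 5 higher and 8 lower and leaving SLC25A4 out of the totals gave 2 higher and 0 lower in limma, with 896 genes at an unadjusted p under 0.05. Voom on the estimated reads gave 3 higher and 1 lower. Lower in the main test were the histone gene HIST2H2BE (-0.35, adjusted p = 0.043), CXCR4 (-0.33, adjusted p = 0.0343), PI4KAP1 (-0.31), the choline kinase CHKB (-0.29), KIAA0907 (-0.25), HAGHL (-0.25), LOC730101 (-0.23) and the interferon signalling factor STAT2 (-0.19, adjusted p = 0.0463). KIAA0907 was not called with the GC trend removed (-0.27, adjusted p = 0.0538), at a fold change as large as before. PAXIP1-AS1 (-0.31), an antisense transcript, and the near-identical FAM226A and FAM226B (-0.29 each, with identical values) are uncertain. CCND1 (0.16, adjusted p = 0.0937) and ATF3 (-0.17, adjusted p = 0.0951) were not called.

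Several protein homeostasis lists were called by camera with the triple mutant, at small median changes. Mitochondrial chaperones and proteases were not called (adjusted p = 0.174), with 0 of 20 members called. The heat shock list rose, with 25 of 28 members positive and a median of 0.075 (adjusted p = 2.44e-06, but adjusted p = 0.777 with an estimated correlation). None of its members was called and 3 passed when adjusted over the list alone, and HSPA1B, an uncertain gene because HSPA1A is a near-identical copy, was at 0.27 (adjusted p = 0.0882). Cytosolic ribosome genes had a median of 0.052 with 75 of 78 members positive (adjusted p = 7.62e-07), mitochondrial ribosome genes 0.049 with 61 of 73 (adjusted p = 0.000794), and import genes 0.051 with 25 of 27 (adjusted p = 0.00145). For each of these 3 lists the estimated correlation gave adjusted p = 0.815 and no member was called. Adjusted over the list alone 0, 1 and 0 members passed, and MRPS18C was at 0.19 (adjusted p = 0.0893). Proteasome genes (median 0.036, adjusted p = 0.0132, but adjusted p = 0.815 with an estimated correlation, and median 0.0107, adjusted p = 0.0814 with the GC trend removed) and mTORC1 genes (0.051, adjusted p = 0.0351, but adjusted p = 0.777 with an estimated correlation and 0.101 by voom) were called higher with 0 members called or past the list-alone test. Genes of the unfolded protein response of the endoplasmic reticulum were called lower (median -0.028, adjusted p = 0.00286, but adjusted p = 0.777 with an estimated correlation), with 0 of 19 called, 1 lower adjusted over the list alone, and the chaperone HSPA5 at -0.17 (adjusted p = 0.126). Glycolysis and hypoxia genes were called lower (-0.028, adjusted p = 0.00142, but adjusted p = 0.815 with an estimated correlation), with 0 members called, 5 adjusted over the list alone, and the glucose transporter SLC2A1 at -0.19 (adjusted p = 0.211). The median deviation of vector replicate 3 (-0.011) lay below that of triple replicate 1 (0.00474), and triple replicate 2 (0.11) lay above vector replicate 2 (0.0971). Cholesterol synthesis genes were called lower as well (-0.031, adjusted p = 0.0302, but adjusted p = 0.494 with an estimated correlation), with 0 members called and 1 adjusted over the list alone. Autophagy genes were not called as a list (adjusted p = 0.726), and 0 of 23 members were called.

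With single libraries left out, which again weakens the test, the calls for the triple mutant changed as well. Their number was 2 without triple replicate 1 or 2 or vector replicate 2 or 3, 3 without triple replicate 3, 8 without quadruple replicate 2, 9 without vector replicate 1, and 30 without wildtype replicate 1 or 3, and only EGR1 and SLC25A4 were called in each of these cases. The unfolded protein response, glycolysis and cholesterol lists (adjusted p = 0.0516 each), the proteasome list (0.157) and the mTORC1 list (0.153) were lost without vector replicate 2, the mTORC1 list without triple replicate 1 (adjusted p = 0.0586) and the cholesterol list without triple replicate 3 (adjusted p = 0.0595) or vector replicate 3 (adjusted p = 0.0897).

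With the quadruple mutant EGR1 rose 1.84-fold over vector to 3.8 ± 0.174 RPKM (log2 fold change 0.65, adjusted p = 0.00192), CCDC85B 1.61-fold from 7.1 ± 0.374 to 11.4 ± 0.173 RPKM (0.62, adjusted p = 0.000873) and PHLDA2 1.55-fold from 4.92 ± 0.0268 to 7.64 ± 0.736 RPKM (0.54, adjusted p = 0.000522). MIR210HG fell to 1.34 ± 0.164 RPKM (-0.73, adjusted p = 0.0226). Against vector, the quadruple mutant gave 112 called genes in all, 88 higher and 24 lower, with a median size of 0.25 apart from SLC25A4. Voom on the estimated reads gave 49 higher and 32 lower, and removing the GC trend gave 60 higher and 31 lower, a total of 91 against 108 for wildtype ANT1. Higher were also SCAND1 (0.59), ZCCHC12 (0.53), the differentiation inhibitor ID1 (0.44), TRAPPC5 (0.44), HIST3H2A (0.42), the complex I subunit NDUFS7 (0.42, adjusted p = 0.0131), CCND1 (0.20) and MYC (0.19). Lower were DKFZP434I0714 (-0.38), HIST1H1C (-0.37), LINC01560 (-0.33), the collagen crosslinking enzyme LOX (-0.33), SLC2A1 (-0.31), CXCR4 (-0.31), CHKB (-0.28), ATF3 (-0.17) and the uncertain antisense transcripts NFYC-AS1 (-0.29) and CAPN10-AS1 (-0.26). The genes called higher had a median transcript GC content of 63.8% against 52.2% for all tested genes, and 68 of the 112 were still called when the GC trend of each library had been removed. HIST3H2A (0.41, adjusted p = 0.0645) and CCND1 (0.12, adjusted p = 0.0878) were then not called, nor were both antisense transcripts (-0.30 and -0.27, adjusted p = 0.0552 each, at fold changes as large as before).

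Several mitochondrial and ribosomal genes were among those calls. Mitochondrial ribosome genes rose as a list, with 62 of 73 members positive and a median of 0.057 (adjusted p = 0.000129, but adjusted p = 0.588 with an estimated correlation). Called members were MRPL55 (0.35, adjusted p = 0.0226), MRPL41 (0.30), MRPS26 (0.23) and MRPS18C (0.18), and 10 passed when adjusted over the list alone. With the GC trend removed MRPL41 (0.096, adjusted p = 0.413), MRPS26 (0.16, adjusted p = 0.0739) and MRPS18C (0.18, adjusted p = 0.0622) were not called, and MRPL55 was. Respiratory chain genes of the nucleus were not called as a list (adjusted p = 0.511), but NDUFS7, COX5B (0.25, adjusted p = 0.0134) and ATP5D (0.40, adjusted p = 0.0235) rose. Cytosolic ribosome genes rose as a list (median 0.047, adjusted p = 0.000129, but adjusted p = 0.588 with an estimated correlation) with RPLP1 (0.14) and RPS28 (0.18) called and 3 of 78 higher when adjusted over the list alone. Heat shock genes had 27 of 28 members positive and a median of 0.08 (adjusted p = 0.000129, but adjusted p = 0.533 with an estimated correlation), with the uncertain copy HSPA1B called (0.33, adjusted p = 0.0157) and 1 past the list-alone test. Import genes (0.059, adjusted p = 0.00698) and mitochondrial chaperones and proteases (0.044, adjusted p = 0.0372) were called higher, each with adjusted p = 0.588 with an estimated correlation, and the nuclease ENDOG of the second list was called (0.24, adjusted p = 0.0362, but 0.10 and adjusted p = 0.254 with the GC trend removed). Adjusted over the list alone 0 import genes and 1 chaperone or protease passed. NF-kB, AP-1 and immediate-early genes were called higher (median 0.102 over 14 genes, adjusted p = 0.00819, but adjusted p = 0.525 with an estimated correlation), with EGR1 and MYC called, 6 adjusted over the list alone, and JUNB at 0.31 (adjusted p = 0.0729). Glycolysis and hypoxia genes were lower (-0.107, adjusted p = 1.48e-07, but adjusted p = 0.525 with an estimated correlation), with SLC2A1 and ENO2 (-0.23, adjusted p = 0.0475) called and 8 adjusted over the list alone. The median deviation of vector replicate 3 (-0.011) lay below that of quadruple replicate 3 (0.00121), while vector replicates 1 and 2 were at 0.133 and 0.0971. Genes of the unfolded protein response were lower (-0.049, adjusted p = 0.00136, but adjusted p = 0.525 with an estimated correlation) with 0 called, 6 lower and 1 higher over the list alone, and HSPA5 at -0.14 (adjusted p = 0.12). Lysosome genes (-0.045, adjusted p = 0.00136, but adjusted p = 0.533 with an estimated correlation) had 0 called or past the list-alone test, as in PSAP (-0.11, adjusted p = 0.199). Cholesterol synthesis genes had a median of -0.025 (adjusted p = 0.0421, but adjusted p = 0.525 with an estimated correlation and 0.0503 by voom), while the fatty acid synthase FASN of that list rose (0.30, adjusted p = 0.0343) and 1 member was higher and 2 lower over the list alone. In the histone list, which was not called (adjusted p = 0.102), H2AFX rose (0.27, but 0.14 and adjusted p = 0.13 with the GC trend removed) and HIST1H1C fell. In the integrated stress response list, which was not called (adjusted p = 0.121), CEBPB rose (0.26, adjusted p = 0.0427, but 0.14 and adjusted p = 0.222 with the GC trend removed) and ATF3 fell. The autophagy list had 0 of 23 members called (adjusted p = 0.497), with a median of 0.011 and a mean of -0.0078. For each list call, median, mean and direction of the test had the same sign in the comparison where camera made it.

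The count for the quadruple mutant was 12 without vector replicate 2, 15 without vector replicate 3, 19 without quadruple replicate 2, 20 without quadruple replicate 3, 36 without quadruple replicate 1, 66 without triple replicate 1, 72 without triple replicate 2, 244 without vector replicate 1 and 254 without wildtype replicate 3, and 9 genes were called throughout, among them EGR1, CCDC85B, PHLDA2, ZCCHC12 and LINC01560. A fit of the 2 groups alone called 187. The chaperone, lysosome, NF-kB and cholesterol lists were lost without vector replicate 2 (adjusted p = 0.0774, 0.0913, 0.0516 and 0.0719), the chaperone, import, cholesterol and cytosolic ribosome lists without quadruple replicate 1 (0.0704, 0.0548, 0.0704 and 0.0704), the chaperone and cholesterol lists without vector replicate 3 (0.144 and 0.0937), and the cholesterol list without quadruple replicate 2 (0.0615).

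Fold changes against vector were compared between the 3 constructs. CXCR4, EGR1, ZCCHC12 and the copies FAM226A and FAM226B were called against vector with each construct, all in 1 direction per gene. With SLC25A4 left out, over the 58 genes called for wildtype or triple mutant, the fold changes correlated at r = 0.901 across genes. Unchanged groups simulated 100 times gave 0.69. All libraries were simulated there, with vector libraries shared by the constructs and noise independent between genes. Wildtype and quadruple mutant gave 0.696 over 149 genes (simulated 0.676), and triple and quadruple mutant 0.762 over 116 genes (simulated 0.692). The sign was the same in 98.3%, 88.6% and 84.5% of these genes, against 92.8%, 91.3% and 91.8% simulated. Over all 6644 genes r was 0.51, 0.446 and 0.562 for these pairs, against 0.5, 0.497 and 0.498 simulated. The covariance was 0.00305, 0.00307 and 0.00366, against 0.0014, 0.00139 and 0.00138 simulated, which leaves 0.00165, 0.00169 and 0.00228. Wildtype and quadruple mutant shared 4 genes called higher and 7 lower, among them ENO2, HIST1H1C and MIR210HG, where independent lists would share 0.34 and 0.083. The triple mutant shared 2 higher and 3 lower with wildtype (0.012 and 0.038 for independent lists) and 2 higher and 7 lower with the quadruple mutant (0.039 and 0.04). In each pair the shared lower genes include FAM226A and FAM226B, whose values are identical, so 1 measurement counts as 2. For each pair, the simulated groups shared 0.01 called higher and 0 called lower on average. The simulated values leave out the effects and any deviation that many genes of a real library share. Those of independent lists leave out the shared controls. Neither is therefore a baseline for what the 3 real vector libraries have in common. With 3 vector libraries the controls cannot be split into parts of at least 2, so part of the excess may come from the shared controls. Genes are not independent replicates.

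Triple mutant against wildtype ANT1 asks what the 3 substitutions add, but the construct mRNA was also higher. Effects of the substitutions and of the amount of construct cannot be told apart here. MAT2A, which makes S-adenosylmethionine, was at 27.8 ± 1.16 RPKM with the triple mutant against 35 ± 1.43 with wildtype (-0.32, adjusted p = 0.0351). Vector libraries had 30.8 ± 1.63, between the 2 constructs. MAT2A and SLC25A4, which was higher (0.93), were the 2 called genes. Median centring left 1 higher and 0 lower, and leaving SLC25A4 out of the totals left 0 in limma, with 789 genes at an unadjusted p under 0.05 and 2 called by voom on the estimated reads with SLC25A4 kept in. Glycolysis and hypoxia genes were higher with the triple mutant than with wildtype (median 0.121, 17 of 20 positive, adjusted p = 2.27e-06, but adjusted p = 0.744 with an estimated correlation). None was called, 11 passed when adjusted over the list alone, and GAPDH was at 0.20 (adjusted p = 0.206) and ALDOA at 0.24 (adjusted p = 0.237). Cytosolic ribosome genes were higher (0.056, 67 of 78 positive, adjusted p = 1.36e-07), unfolded protein response genes lower (-0.062, adjusted p = 0.000964) and lysosome genes lower (-0.045, adjusted p = 0.0177). For each of these 3 lists the estimated correlation gave adjusted p = 0.744, with 0 members called and 0 past the list-alone test, and HSPA5 was at -0.15 (adjusted p = 0.258). Heat shock (adjusted p = 0.361), import (0.931) and autophagy genes (0.2) were not called as lists. Without wildtype replicate 3, 142 genes were called, 58 higher and 84 lower, and MAT2A was not called with the GC trend removed (-0.33, adjusted p = 0.101), nor without any 1 of triple replicates 1 and 2, wildtype replicates 1 and 2, vector replicate 2 or the 3 quadruple replicates, which left 1 call each. Without wildtype replicate 1 the unfolded protein response (adjusted p = 0.09) and lysosome lists (0.195) were lost, the latter also without wildtype replicate 3 (0.073) or triple replicate 1 (0.352).

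Quadruple mutant against wildtype ANT1 gave 117 called genes, 96 higher and 21 lower. SLC25A4 was higher here too, so substitutions and amount of construct again cannot be told apart. The DNA replication licensing factor CDT1 was 1.4-fold higher, at 33.9 ± 1.18 RPKM against 24.2 ± 2.17 with wildtype (0.48, adjusted p = 0.00562) and 28.1 ± 1.22 with vector. CCDC85B was higher by 0.48 (adjusted p = 0.00982), HIST3H2A by 0.62 (adjusted p = 0.0132) and SCAND1 by 0.44 (adjusted p = 0.0305). MAT2A was lower, at 27.1 ± 0.344 RPKM (-0.36, adjusted p = 0.00602). MIR503HG (-0.47), AGER (-0.31), the complex I subunit NDUFB9 (-0.25, adjusted p = 0.0367) and the uncertain antisense NFYC-AS1 (-0.40) were lower too. With vector MIR503HG was at 5.49 ± 0.746 RPKM, close to 5.58 ± 0.287 with the quadruple mutant and below 8.1 ± 0.401 with wildtype. Its difference thus goes with the rise in wildtype cells. Vector levels of MAT2A (30.8 RPKM), AGER (0.961), NDUFB9 (10.9) and NFYC-AS1 (2.1) lay between those with wildtype and with the quadruple mutant. The genes called higher again had a median GC content of 63.8%, and fold changes correlated with GC content across genes at r = 0.417. With the GC trend of each library removed 26 genes were called, 18 higher and 8 lower, of which 21 were among the 117. CDT1, CCDC85B, HIST3H2A, MAT2A, MIR503HG and NFYC-AS1 were among these, while SCAND1 (0.35, adjusted p = 0.0704), NDUFB9 (-0.25, adjusted p = 0.0887) and AGER (-0.35, adjusted p = 0.0541) were not. A fit of the 2 groups alone called 19 genes.

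Of the lists, 3 were called higher and 2 lower with the quadruple mutant than with wildtype. Cytosolic ribosome genes had a median of 0.052 with RPLP1 (0.18, adjusted p = 0.0179) and RPS28 (0.23, adjusted p = 0.0179) called and 10 of 78 adjusted over the list alone (adjusted p = 0.000281, but adjusted p = 0.909 with an estimated correlation). Integrated stress response genes had a median of 0.055 with 24 of 30 positive (adjusted p = 0.0333, but adjusted p = 0.909 with an estimated correlation). The pseudokinase TRIB3 rose (0.13, adjusted p = 0.0292), 7 members were higher and 1 lower when adjusted over the list alone, and PYCR1 was at 0.19 (adjusted p = 0.0664). NF-kB and AP-1 genes had a median of 0.091 (adjusted p = 0.0336, but adjusted p = 0.909 with an estimated correlation, adjusted p = 0.201 and median 0.0515 with the GC trend removed and 0.266 by voom). JUND (0.26, adjusted p = 0.0137) and the phosphatase DUSP1 (0.20, adjusted p = 0.049) rose, EGR1 was at -0.31 (adjusted p = 0.0585), and 4 were higher and 2 lower over the list alone. Unfolded protein response genes were lower (-0.066, adjusted p = 0.00202, but adjusted p = 0.797 with an estimated correlation), with the disulfide isomerase PDIA3 called (-0.18, adjusted p = 0.0369), 5 lower and 1 higher over the list alone and CALR at -0.13 (adjusted p = 0.0718). Lysosome genes were lower (-0.077, adjusted p = 0.000122, but adjusted p = 0.797 with an estimated correlation) with 0 of 22 called, 3 lower over the list alone, and the protective protein CTSA at -0.15 (adjusted p = 0.0585). Outside the called lists COX5B (0.28, adjusted p = 0.0113), NDUFS7 (0.32), MRPS34 (0.25), FASN (0.31), H2AFX (0.25) and the pro-apoptotic BBC3 (0.23, adjusted p = 0.0372) rose. With the GC trend removed COX5B stayed called, but TRIB3 (0.062, adjusted p = 0.298), JUND (0.084, 0.224), NDUFS7 (0.20, 0.0704), MRPS34 (0.15, 0.0687), FASN (0.19, 0.0517), H2AFX (0.12, 0.209) and BBC3 (0.13, 0.12) did not. Nor did DUSP1 (0.19, adjusted p = 0.0759) and PDIA3 (-0.17, 0.1), whose fold changes were nearly as large as before. The heat shock (adjusted p = 0.649), import (0.923) and autophagy lists (0.544) were not called. The gene count was 9 without quadruple replicate 2 or 3, 26 without quadruple replicate 1 and 42 without wildtype replicate 3, and CCDC85B, CDT1, COX5B and MAT2A stayed called whichever library was left out. The integrated stress response list was lost without quadruple replicate 3 (adjusted p = 0.0571) or wildtype replicates 1 (0.115) or 3 (0.249), the NF-kB list without wildtype replicates 2 (0.0957) or 3 (0.331), the unfolded protein response list without wildtype replicate 1 (0.114), and the cytosolic ribosome list without wildtype replicate 1 (0.172) or quadruple replicate 1 (0.0837).

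Quadruple against triple mutant asks what A123D adds. HIST3H2A rose from 3.31 ± 0.248 to 6.17 ± 0.596 RPKM (0.73, adjusted p = 0.00469), CCDC85B 1.71-fold (0.69, adjusted p = 0.000759), SCAND1 by 0.48 (adjusted p = 0.0268), TMEM121 by 0.47 (adjusted p = 0.0121) and the transcriptional repressor HES4 from 18 ± 1.2 to 25.4 ± 0.748 RPKM (0.47, adjusted p = 0.000759). COX5B (0.32, adjusted p = 0.00454), NDUFS7 (0.33, adjusted p = 0.0439) and JUND (0.23, adjusted p = 0.0301) rose as well. The 45 called genes were all higher and limma called 0 lower, with 729 genes of either direction at an unadjusted p under 0.05, 1 lower by voom on the estimated reads and 1 lower with the replicate block. Their median GC content was 65.7%, and fold changes correlated with GC content across the 6528 genes at r = 0.544. With the GC trend removed 6 genes were called, CCDC85B, COX5B, HIST3H2A, MIF, MZT2A and PHLDA2, and the same number with the replicate block added. In the blocked fit without the GC trend HES4 was at 0.18 (adjusted p = 0.482), SCAND1 at 0.40 (0.163), TMEM121 at 0.26 (0.151), NDUFS7 at 0.19 (0.155) and JUND at 0.019 (0.948). The block alone added a call of MRPL41 (0.27, adjusted p = 0.0151, against 0.0897 without it). A fit of the 2 groups alone called 194 genes higher and 10 lower, and the fit without wildtype replicate 3 called 175 higher and 6 lower. MIF, MZT2A (a near-identical copy of MZT2B, so uncertain) and PHLDA2 lie outside the naming rule for this comparison and are listed after their values were seen.

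NF-kB and AP-1 genes were higher with the quadruple than with the triple mutant (median 0.064, 12 of 14 positive, adjusted p = 0.00914, but adjusted p = 0.982 with an estimated correlation, adjusted p = 0.0991 and median 0.0331 with the GC trend removed and 0.24 by voom). JUND was the member called, 3 passed when adjusted over the list alone, and IER2 was at 0.25 (adjusted p = 0.0576). Glycolysis and hypoxia genes were lower (-0.039, adjusted p = 0.0224, but adjusted p = 0.982 with an estimated correlation), with 0 of 20 called or past the list-alone test and LDHA at -0.18 (adjusted p = 0.395). Heat shock genes (adjusted p = 0.842), import genes (0.92), cytosolic (0.817) and mitochondrial ribosome genes (0.709) and autophagy genes (0.842) were not called as lists. The gene count was 9 without triple replicate 3, 10 without quadruple replicate 2 or 3, 13 without triple replicate 2, 18 without triple replicate 1, 22 without quadruple replicate 1, 85 without wildtype replicate 1 and 181 without wildtype replicate 3. CCDC85B, COX5B, HES4 and HIST3H2A were called in each case, while the glycolysis list was lost without quadruple replicate 1 (adjusted p = 0.0679) or 2 (0.0869) or triple replicate 2 (0.653).

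Lists that camera called in none of the 6 comparisons were autophagy (adjusted p = 0.103 to 0.842), nuclear genes of the respiratory chain (0.1 to 0.94), mitochondrial carriers (0.202 to 0.942), interferon-stimulated genes (0.364 to 0.872), p53 and apoptosis genes (0.121 to 0.854), cell cycle genes (0.522 to 0.968) and NRF2 targets (0.141 to 0.968). Single members were called in some of them, such as CCND1, STAT2, SLC25A6, BBC3 and COX5B in the comparisons given for each. Only 5 of 32 interferon-stimulated genes and 13 of 22 p53 and apoptosis genes were tested, so the other members of these lists were not assessed. The 36 list calls made over the 6 comparisons were all lost with an estimated correlation, where the lowest adjusted p was 0.0961.

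**Figure D3:**
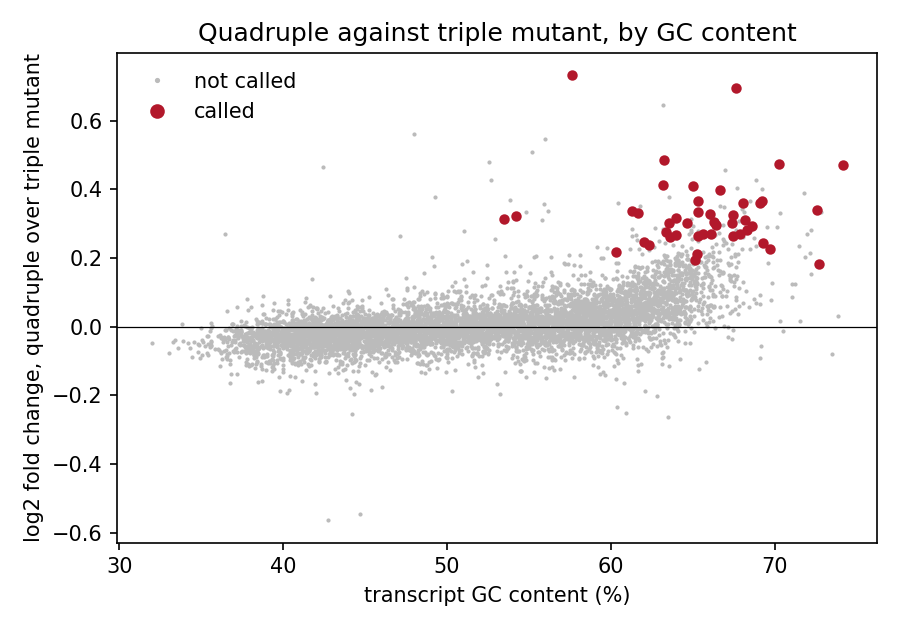
Log2 fold change of the quadruple over the triple mutant against the transcript GC content in percent, with 1 point per tested gene and the called genes in red. The called genes lie above 0 and mostly at high GC content, with a median of 65.7%.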

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

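Voom, the removal of GC and length trends and the fit that combined GC removal with the replicate block were chosen after the data had been seen, and the other alternatives were planned. Counts are given in the order wildtype, triple and quadruple mutant against vector, triple and quadruple mutant against wildtype, and quadruple against triple mutant. An absolute log2 fold change of at least 1 left 1, 1, 1, 0, 1 and 0 called genes by construction, since only SLC25A4 is that large on the log2(RPKM + 1) scale. That scale understates low genes, as in EGR1, which went from 2.07 to 4.98 RPKM with wildtype ANT1 but stayed below 1. Without a filter 20586 genes entered the test and 15, 4, 10, 3, 3 and 7 were called. In fits of the 2 groups compared, which have 6 libraries, 7, 4, 187, 1, 19 and 204 were called. Leaving SLC25A4 out of the totals gave 2 for the triple mutant against vector and 0 against wildtype, where limma had 789 genes at an unadjusted p under 0.05. Median centring gave 1 for the triple mutant against wildtype. Voom gave 4 for the triple mutant against vector and 191 for the quadruple mutant against wildtype. Removal of the GC trend gave 108 for wildtype against vector, 1 for triple mutant against wildtype, 26 for quadruple mutant against wildtype and 6 for quadruple against triple mutant. Removal of the length trend gave 6 for the triple mutant against vector and 1 against wildtype. For these changes in count the cause was not tested, apart from the number of genes or libraries named. With 1 library left out the counts ranged from 7 to 74, 2 to 30, 12 to 254, 1 to 142, 9 to 168 and 9 to 181. Apart from the replicate block, the other alternatives kept each count within 1.5 times the main one.

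Of the lists, 0 stayed called in any of the 6 comparisons with an estimated correlation, and fry, which does not compare a list with other genes, called 2, 0, 0, 0, 0 and 0. Voom called 1 list between quadruple and triple mutant. With 1 library left out 4 to 9, 4 to 12, 6 to 10, 2 to 6, 2 to 6 and 1 to 3 lists were called. The log2 fold change of SLC25A4 ranged from 5.95 to 6.11, 6.89 to 6.98, 7.27 to 7.37, 0.83 to 0.99, 1.21 to 1.37 and 0.34 to 0.43 in the same fits. Between quadruple and triple mutant SLC25A4 (0.38) was called with a minimum of 5 RPKM (0.38, adjusted p = 0.0105), a pseudocount of 5 (0.38, 0.0449), only the 2 groups (0.38, 0.012) and voom (0.38, 0.0149), and its adjusted p ran from 0.0047 to 0.314 over all alternatives. The correlation of fold changes between constructs was lower over all tested genes than over called ones, at 0.51, 0.446 and 0.562. Over the alternatives, the values of named genes kept direction and side of the threshold in 12761 cases, lost the call in 740, gained it in 207 and turned the direction past the threshold in 0. The minimum of 1 RPKM, on values divided by gene span, limited which genes were tested more than depth did. At least 10 estimated reads in at least 3 libraries were reached by 14261 names, while 6645 passed that minimum.

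The replicate number as a block gave 28, 4, 124, 2, 116 and 50 called genes. Numbers paired the libraries only between quadruple and triple mutant, where each of the 3 quadruple libraries correlated best with its own number. There the block added the calls of SLC25A4 (0.38, adjusted p = 0.0244) and MRPL41, kept 39 of 45 genes and changed no other call of a named gene or list, and with the GC trend removed too 6 genes were called. In the other comparisons the libraries share only a number. Correlations of same-numbered libraries ran from -0.218 to 0.209, and 1, 0, 2, 1 and 0 of 3 libraries correlated best with their own number. There the block called the histone list between triple mutant and wildtype (adjusted p = 0.0494) and left all other list calls as they were.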

Other observations

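Voom, the removal of GC and length trends, the tests of the whole fold change, the count of lost calls with a smaller fold change and the standard errors used in the hypoxia tests were chosen after results had been seen, and so were the genes named here. Among genes below the minimum RPKM of the limma test, voom on estimated reads called 14 for wildtype ANT1, 12 for the quadruple mutant and 0 for the triple mutant against vector. Over genes of all levels, voom had 1522 at an unadjusted p under 0.05 for the triple mutant. In wildtype ANT1 cells the transcription factors ETV5 (log2 fold change 1.06 ± 0.149, adjusted p = 0.00299) and ETV1 (1.1, adjusted p = 0.0465) and the receptor signalling inhibitor SPRY4 (1.97 ± 0.387, adjusted p = 0.0367) rose. ETV5 went from 56.3 to 131 estimated reads per library on average, and SPRY4 only from 5.99 to 24.6. ETV5 also rose with the quadruple mutant (0.84, adjusted p = 0.0249) and was at 0.66 with the triple mutant (adjusted p = 0.119). PFKFB4, a regulator of glycolysis induced by hypoxia, fell with wildtype ANT1 (-0.55, adjusted p = 0.00324) and the quadruple mutant (-0.45, adjusted p = 0.0142), as did PPFIA4 (-0.58, adjusted p = 0.0373, and -0.61, adjusted p = 0.0288). P4HA1, a collagen hydroxylase, fell with the quadruple mutant (-0.44, adjusted p = 0.0399), where ZNF503 rose (0.53, adjusted p = 7.74e-05). These values were not computed with single libraries left out.

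ETV5, SPRY4, CCND1 and EGR1 are known targets of ERK signalling, and a hypothesis is that its output was higher with ANT1. It was tested on 6 other targets, SPRY2, ETV4, DUSP4, EPHA2, EPHA4 and PHLDA1, with voom. Their median log2 fold change was 0.0393 ± 0.0364 with wildtype ANT1, which leaves the hypothesis open there. It was -0.0833 ± 0.0391 with the triple and -0.0519 ± 0.0506 with the quadruple mutant, which argues against a rise of these targets as a set. Of the 6 targets 2 were positive with each mutant. ETV4 alone was at 0.59, 0.66 and 0.49 (adjusted p = 0.259, 0.231 and 0.302). Outside the 6, SPRY4 (1.24, adjusted p = 0.271), ETV1 (0.89, 0.166) and DUSP6 (0.15, 0.909) were positive but not called by voom with the triple mutant. The same held with the quadruple mutant for SPRY4 (0.99, adjusted p = 0.302), ETV1 (0.53, 0.355) and DUSP6 (0.32, 0.709). With wildtype ANT1 DUSP6 was at -0.0498 ± 0.324 (adjusted p = 0.971 by voom). Its group means were only 15 to 23 estimated reads.

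All 45 genes called between quadruple and triple mutant were higher. With the GC trend of each library removed in the blocked fit 6 were called, which is consistent with GC content bias between libraries as the source of most calls. Of the 33 calls lost there, 31 had a fold change smaller by more than 1 standard error (median 0.306 ± 0.0496 before and 0.164 ± 0.039 after over the 33) and 4 had a p below the cutoff before removal. Without the block 39 calls were lost, of which 36 had such a smaller fold change and 14 a p below the earlier cutoff. All 45 had a median of 0.17 (quartiles 0.135 to 0.24) after removal and 1 changed sign, so GC content as the source of the whole fold change stays undecided. For transcript length the median of the 45 stayed at 0.303, all 45 stayed called without the block, and with it 28 of 39 did, where 0 of the 11 lost had a fold change smaller by more than 1 standard error (median 0.268 ± 0.0496 before and 0.264 ± 0.0513 after), which argues against length as the source of the calls or of the fold change. The A123D substitution and the higher SLC25A4 level go with the same libraries as the GC trend and stay untested.

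Glycolysis and hypoxia genes were lower with wildtype ANT1 than with vector, with a median of -0.156 ± 0.0463 (standard error between libraries). If 1 library out of line were the cause, leaving it out would bring the median to -0.08 or above, and the highest value was -0.134 ± 0.0455, without vector replicate 1. That is below the -0.12 set beforehand as evidence against this explanation, but by less than a standard error, so 1 library out of line stays undecided. With the GC trend removed the median was -0.152, below the same bound by less than the standard error between libraries (0.0435), the spread used first, which left GC content bias undecided. The standard error of the shift made by the correction, used second because both values come from the same libraries, was 0.0137, and with it the -0.152 argues against GC content bias as the whole source, while the list call was lost with an estimated correlation (adjusted p = 0.276).

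Heat shock, import, cytosolic ribosome and mitochondrial ribosome genes were higher as lists with the triple and quadruple mutants than with vector. The shift rests mainly on vector replicates 2 and 3, which lay below all 6 mutant libraries in each list, while the median of vector replicate 1 lay above 0, 2, 3 and 4 of the 6. Of these 8 list tests 8 stayed called with the length trend removed and 8 with the GC trend removed, which argues against either bias as the whole source. The lowest RPKM totals were those of wildtype replicate 1 (73361.2), vector replicate 2 (73431.7) and vector replicate 3 (74013.9). In each of the 4 lists these libraries also had the lowest medians, and whether the shift follows the RPKM total was not tested. An effect of the mutants or of the amount of ANT1 may remain as a hypothesis, but 0 of the 8 list tests were called by camera with an estimated correlation, and the heat shock, import and mitochondrial ribosome lists were also called for wildtype ANT1. Whether the mutants exceeded wildtype was tested directly, and of the 4 lists only the cytosolic ribosome list was called in both comparisons (adjusted p = 0.744 for the triple and 0.909 for the quadruple mutant with an estimated correlation). Libraries overlapped in that list. The median of wildtype replicate 2 (0.0104) lay above those of triple replicate 3 (-0.00866) and quadruple replicate 2 (-0.00518), while wildtype replicate 1 was lowest (-0.0798). The call for the quadruple mutant was lost without wildtype replicate 1 or quadruple replicate 1.

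With 3 libraries against 3 there are 10 splits, and the smallest share they can give is 0.1. The real splits gave 50, 15, 112, 2, 117 and 45 called genes for wildtype, triple and quadruple mutant against vector, triple and quadruple mutant against wildtype, and quadruple against triple mutant. The highest of the other splits gave 1, 0, 0, 2, 0 and 0, so that 1, 1, 1, 2, 1 and 1 of the 10 splits reached the real count.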
